A study of Homo sapiens with 6 samples.

How the data were processed

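RNA was sequenced from SCC-15, an established human line grown from an oral squamous cell carcinoma, after transfer of one of 2 plasmids. Per the labels, 3 libraries came from cells given the plasmid PB-IP-PPARG (the PPARG group) and 3 from cells given the plasmid PB-IP-2flag (the control group). PPARG encodes peroxisome proliferator-activated receptor gamma, a nuclear receptor that pairs with a retinoid X receptor and switches on genes of lipid uptake, storage and oxidation. Cells were grown in DMEM/F-12 with serum, RNA was taken with Trizol, and libraries were made from total RNA with the NEBNext Ultra II RNA kit, per the labels' protocols. The labels name no receptor agonist and no time of harvest. The series' design text speaks of experiments done in duplicate, whereas the labels and the table hold 3 libraries per group. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

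The deposited table gives 1 value per gene and library for 19970 genes, with a gene ID and a symbol. Its header does not name the unit. The values were read as FPKM that the authors deposited, fragments per kilobase of exon and per M (mega) reads on genes, because the values of many low genes were near multiples of a step that was smaller for longer genes and deeper libraries. Per the submitters' processing notes, HISAT2 2.0.5, HTSeq 0.9.1 and DESeq 1.30.0 were used, and the notes name the build mm9, a mouse build. The gene IDs are human Ensembl IDs, 19897 of them were found in GENCODE release 29 (build GRCh38) and 73 were not, and the union exon lengths of that release gave the steps. The setting for strand is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. Reads from the plasmid's PPARG and from the cell's own gene are also counted together.

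Depth was recovered from the low values. A read step was found for 2245 low genes, and 1078 of them (48.02%) gave depths within 0.1% of the common depth. The depths were 17.7, 14.2 and 17.6 M reads for control replicates 1, 2 and 3 and 16.8, 16.1 and 19.0 M reads for PPARG replicates 1, 2 and 3. The reads implied by FPKM, length and depth add up to the same totals over the listed genes. About 65% of the values worth 0.5 to 100 reads came out whole within 0.05 of a read, so the implied reads are approximate. They served for an alternative test, for the comparison of replicates and for the means and dispersion of the simulated data. They also showed how many reads stood behind a low value and gave the ratios of PPAR targets under the filter. Those results share the approximation. At these depths a gene at 1 FPKM rests on few reads when it is short. All 6 value columns were matched to samples by their titles, and no column was left unmatched.

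The main test was limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1) of the genes with at least 1 FPKM in at least 3 libraries. It compared the 3 PPARG libraries with the 3 control libraries with no other term, and p-values were adjusted by the method of Benjamini and Hochberg. A gene was called at an adjusted p under 0.05. The design had named a count-based test for the case that the table held counts, and the limma test for normalized values; the second applied. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and folds of mean FPKM are given beside some of them. Group values are means ± SD over 3 libraries. PPARG was also tested alone by an exact two-sided permutation test, which cannot go below 0.1 with 3 libraries against 3.

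A set of 29 gene lists was fixed before the data were examined, PPARG being in none of them. Lists with at least 5 tested members, 27 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists, and beside it with camera's estimated correlation and with fry. The genes named in the text were set by a rule fixed at the same time: PPARG, the 12 largest rises and 12 largest falls among called genes with a mean of at least 2 FPKM in the higher group, an ordinary symbol and no overlap between the libraries of the groups, and up to 4 members of each list with the smallest adjusted p. This gave 123 genes. Results for some genes that the rule names are not reported here. Any other gene is said to have been chosen after its values were seen.

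Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, rescaling by trimmed means of log ratios (TMM, trims of 30% and 5%), limma without the trend, a stricter threshold of 0.01, a log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. Alternatives added after seeing the data were a correction of each library for GC content and gene length by loess with a span of 0.5, that correction without PPARG replicate 3, and limma's voom on the implied reads. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

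The steps were first tested on simulated data for PPARG against control over 10636 genes. The main test found 82% of genes changed 1.25-fold, 98% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold. It called 196 genes, 8 of them unchanged, and 0 genes when none was changed. Fitted log2 fold changes were 0.88 to 0.901 of the true ones. A simulated GC trend with no changed gene gave 444 calls before and 0 after the GC and length correction. That trend was stronger than the one in the data (Spearman of log2 fold change with GC -0.769 against -0.204). The simulated genes were independent and shared a dispersion of 0.00102.

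Replicates were compared before they were averaged. A chi-square per gene on the implied reads was 2.399 to 3.629 between control libraries, 2.905 to 5.939 between PPARG libraries and 6.513 to 13.83 between groups, so no pair of libraries lay within sampling noise. The highest value within a group was between PPARG replicates 1 and 3.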

Results

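Gene expression was measured by RNA sequencing in 6 libraries of the SCC-15 oral carcinoma line, 3 from cells given a PPARG plasmid and 3 from cells given a control plasmid. The comparison asks which transcripts differ when PPARG is overexpressed in these cells. Depth ranged from 14.2 to 19.0 M reads (M, mega), and 10477 to 10692 genes per library reached 1 FPKM. Of 19970 listed genes, 3415 were at 0 in all libraries and 10651 were tested. In a principal component analysis the first component held 54% of the variance and separated the groups, with the control libraries at -8.496, -7.358 and -6.807 and the PPARG libraries at 5.101, 6.394 and 11.17.

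PPARG transcripts were 34.2-fold more abundant in the PPARG libraries. The control libraries held 4.85, 4.36 and 5.07 FPKM and the PPARG libraries 160.4, 164.3 and 163.1 FPKM, so every library followed its label. The means were 4.76 ± 0.362 and 162.6 ± 2.03 FPKM, a log2 fold change of 4.83 (SE 0.0496, limma adjusted p = 8.77e-15). PPARG (ENSG00000132170) lies on chromosome 3 at 12287368 to 12434356 of GRCh38. The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. The plasmid's transcript and that of the cell's own gene were not separated.

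Outside PPARG, changes were many and small. SERPINB3, SERPINB4 and KRT14 fell by over 1 log2 unit, ANKRD1 and SLC12A3 rose several-fold from low levels, and most other calls were modest. Of the tested genes 461 were higher and 763 lower in the PPARG libraries (limma, adjusted p under 0.05), 1224 in all, and their median absolute log2 fold change was 0.255. A log2 fold change of at least 1 was reached by 3 genes upward, PPARG, ANKRD1 and SLC12A3, and by 3 downward, SERPINB3, SERPINB4 and KRT14. Libraries of the groups did not overlap for 3404 tested genes (31.96%), against an average of 10% if the libraries were exchangeable. Genes vary together, so in a single grouping that share can lie far from 10%. Its spread was not estimated, and the comparison is not a test. After correction for GC content and length, an alternative chosen after seeing the data, 680 genes were higher and 651 lower. The count of called genes was 430 with no filter, 472 without control replicate 1, 681 without control replicate 3, 697 without PPARG replicate 2 and 567 without PPARG replicate 3.

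**Figure D1:**
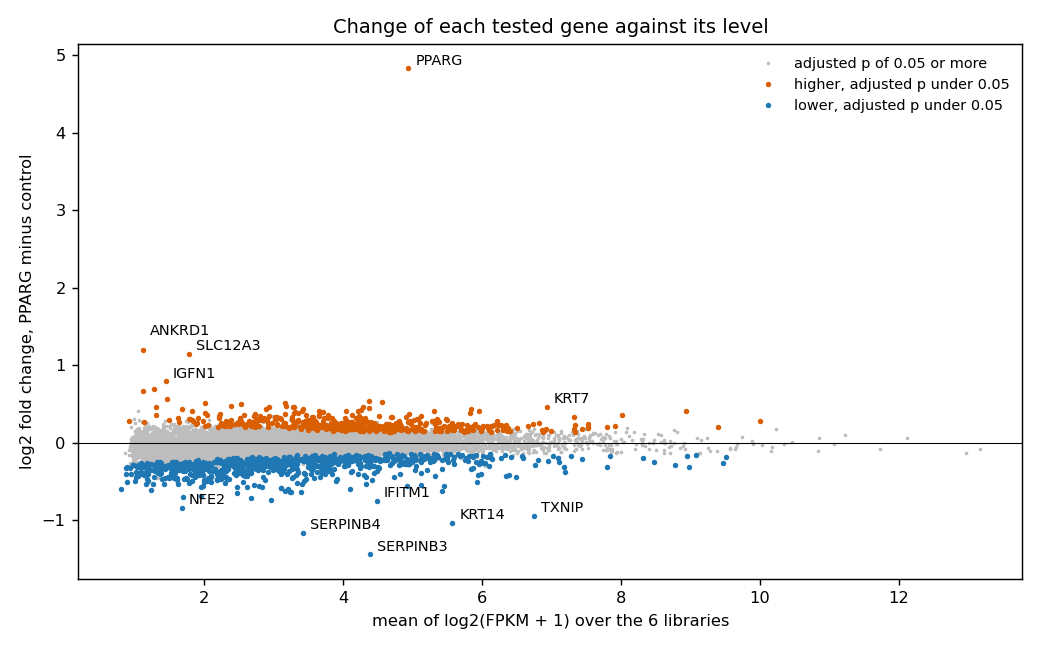
Log2 fold change (PPARG minus control, on the log2(FPKM + 1) scale) of each of the 10651 tested genes against its mean log2(FPKM + 1) over the 6 libraries, with the 461 higher genes in orange, the 763 lower genes in blue and the rest in grey. PPARG stands alone at 4.83, and nearly all other called genes lie within 1 log2 unit of 0.

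The largest rise after PPARG was that of ANKRD1, an ankyrin repeat protein known as a transcriptional target of YAP. It went from 0.439 ± 0.16 to 2.30 ± 0.298 FPKM (5.23-fold, log2 fold change 1.20, limma adjusted p = 5.87e-05) and lies on chromosome 10 at 90912096 to 90921276. SLC12A3, the thiazide-sensitive sodium chloride cotransporter of the kidney, rose from 1.35 ± 0.524 to 4.16 ± 0.831 FPKM (log2 1.14, adjusted p = 0.000703). IGFN1, a muscle protein with immunoglobulin and fibronectin domains, rose from 1.07 to 2.61 FPKM and IFNE, which encodes interferon epsilon, from 1.28 to 2.38 FPKM. Among better expressed genes, placental alkaline phosphatase (ALPP) rose from 16.3 ± 0.496 to 23.9 ± 1.3 FPKM and the Wnt antagonist DKK1 from 18.7 ± 0.554 to 27.3 ± 2.22 FPKM (log2 0.53 and 0.52, adjusted p = 0.000141 and 0.000288). UCN2, a peptide of the corticotropin-releasing factor family, the Fos-family subunit FOSL1, OASL, KRT19 and the tRNA methyltransferase METTL1 rose by log2 0.51, 0.51, 0.50, 0.47 and 0.47. The defensin DEFB131B rose by 0.69, but on only 2 to 9 implied reads per library, and its call was lost with voom (adjusted p = 0.0631). Without control replicate 1 the calls of FOSL1 and METTL1 were lost (adjusted p = 0.0551 and 0.0596), METTL1 also without control replicate 3 or PPARG replicate 3, and both and OASL with no filter.

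SERPINB3 and SERPINB4, neighbouring genes of the squamous cell carcinoma antigens, showed the steepest falls. SERPINB3 (chromosome 18, 63655197 to 63661963) went from 33.4 ± 1.47 to 11.8 ± 2.45 FPKM (log2 fold change -1.44, limma adjusted p = 2.34e-05) and SERPINB4 from 15.1 ± 1.45 to 6.24 ± 1.19 FPKM (-1.16, adjusted p = 0.00012). Their sequences are nearly identical, so the split of reads between them is uncertain. TXNIP (chromosome 1, 145992435 to 145996600), an arrestin that binds thioredoxin and restrains glucose uptake, fell from 147.6 ± 4.22 to 76.2 ± 4.86 FPKM (-0.95, adjusted p = 8.19e-07). NFE2, a transcription factor of the erythroid lineage, fell by 0.84 on the log2 scale and IFITM1, an interferon-induced membrane protein, from 28.1 ± 1.40 to 16.3 ± 1.12 FPKM (-0.75, adjusted p = 2.34e-05). The matrix protein ADAMTSL4, the cytokine receptor chain IL20RB, the mitochondrial nucleotidase NT5M, the cytochrome oxidase subunit COX6B2, KRT16 and the nerve growth factor receptor NGFR had log2 changes of -0.73, -0.72, -0.70, -0.69, -0.65 and -0.64. The call of NT5M was lost with no filter (adjusted p = 0.102), without control replicate 1 (0.0677) and without PPARG replicate 3 (0.0533).

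Known PPAR target genes did not rise as a group despite the PPARG level. Of 38 listed targets 18 were expressed enough to be tested: CPT1A, which starts mitochondrial fatty acid import, rose from 10.2 ± 0.0977 to 12.5 ± 0.507 FPKM (log2 0.27, limma adjusted p = 0.00658), and the carnitine carrier SLC25A20 from 6.37 ± 0.496 to 8.28 ± 0.557 FPKM (0.33, adjusted p = 0.00902, lost with no filter at 0.0541). TXNIP fell, and 15 did not pass. Their count of higher and lower calls was 2 and 2 without PPARG replicate 1. Adjusted over the list alone, 3 were higher and 3 lower. The list's median log2 fold change was -0.00265 and its mean -0.0365, while camera's direction was upward with an adjusted p of 0.965. ACADVL was at 81.9 ± 2.60 and 82.9 ± 4.45 FPKM and HILPDA at 7.39 ± 0.702 and 7.22 ± 0.962 FPKM in control and PPARG libraries, neither past the threshold. Some targets that did not pass still had no overlap between the libraries of the groups. CAT went from 24.1 ± 0.712 to 26.4 ± 0.952 FPKM and MGLL from 1.94 ± 0.0912 to 1.53 ± 0.197 FPKM. ACADVL, HILPDA, CAT and MGLL were chosen after their values were seen.

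The classical adipocyte targets lay under the filter of 1 FPKM in both groups. FABP4 was at 0.355 ± 0.192 FPKM in control and 0.345 ± 0.112 FPKM in PPARG libraries, on 25 and 24 implied reads over the 3 libraries of each group. ANGPTL4 was at 0.290 and 0.315 FPKM, and PDK4, a kinase that shuts off pyruvate oxidation, at 0.878 and 0.899 FPKM on 198 and 210 implied reads. The 20 targets under the filter were not tested gene by gene, and CIDEA, ADIPOQ and CIDEC were listed at 0 in all 6 libraries. Not all of the 20 were flat. UCP3 was at 0.106 and 0.246 FPKM in control and PPARG libraries, on 20 and 47 implied reads. PLIN5 went the other way, at 0.109 and 0.029 FPKM on 26 and 7 implied reads. In both the libraries of the groups did not overlap. These genes were chosen after their values were seen. Among adipocyte markers 2 of 18 could be tested and neither passed: CEBPA was at 2.26 ± 0.296 and 1.83 ± 0.209 FPKM and CFD at 32.7 ± 1.49 and 31.5 ± 0.879 FPKM. In the list of PPAR and RXR receptors and cofactors, CEBPB (93.0 ± 5.56 to 68.6 ± 1.21 FPKM, log2 -0.43, limma adjusted p = 0.000288) and CEBPD (39.0 ± 3.92 to 29.5 ± 1.91 FPKM, -0.39), transcription factors that act with PPARG in fat cells, fell. They were 2 of 17 members, 0 rose (0 higher and 3 lower over the list alone), and the camera adjusted p was 0.457. The call of CEBPD was lost with no filter (adjusted p = 0.0531) and after GC and length correction without PPARG replicate 3 (0.137). RXRA, the partner receptor, chosen after its values were seen, was at 17.4 ± 0.379 and 17.9 ± 0.675 FPKM (adjusted p = 0.634).

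**Figure D2:**
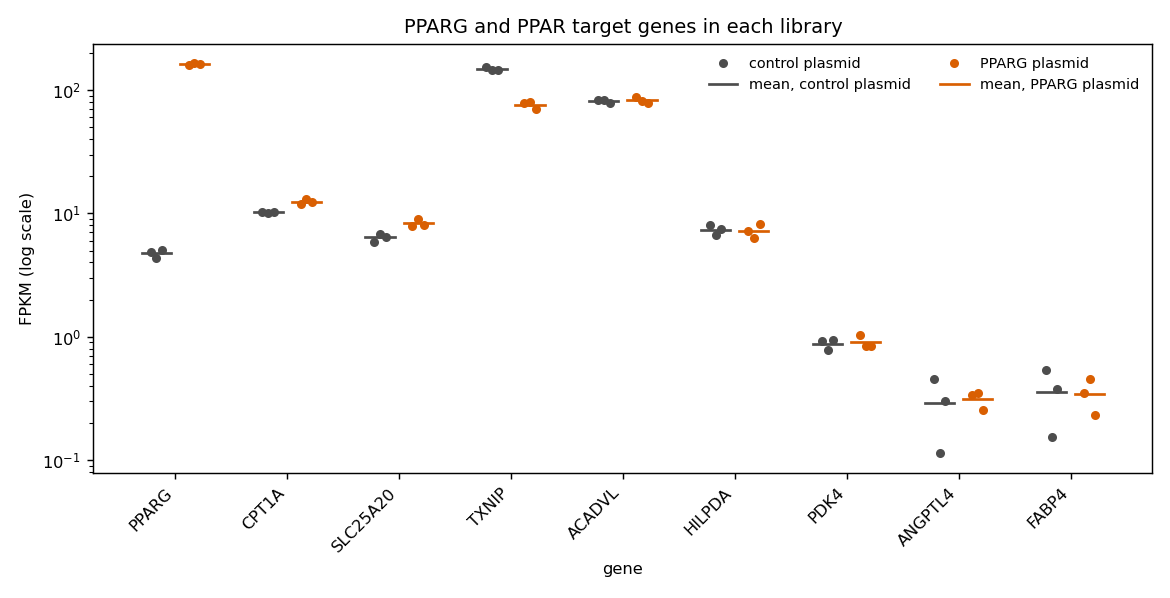
FPKM (log axis) of PPARG and 8 PPAR target genes in each library, control plasmid in grey and PPARG plasmid in orange, with 1 dot per library and bars at the group means. PPARG rises from 4.76 to 162.6 FPKM and TXNIP falls from 147.6 to 76.2 FPKM, while CPT1A and SLC25A20 rise slightly and the dots of the other 5 genes overlap. Targets under the filter that moved more on few reads, UCP3 upward and PLIN5 downward, are not drawn.

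Lipid lists had few called members. In fatty acid oxidation 2 of 22 genes rose (CPT1A and SLC25A20), ACADS fell from 9.72 ± 0.174 to 8.56 ± 0.228 FPKM and 19 did not pass, with a median log2 fold change of 0.05. Adjusted over the list alone, 6 were higher and 1 lower. The fry adjusted p was 0.00207. The camera adjusted p was 0.0442, and the adjusted p was 0.568 with an estimated correlation. That call held in 6 of 15 alternatives (adjusted p 0.0304 to 0.0781), being lost without control replicate 1, control replicate 2, PPARG replicate 1 or PPARG replicate 3 (0.0645, 0.0509, 0.067 and 0.0584). The call of ACADS was kept in 0 of the 6 fits with a library left out, and after GC and length correction its log2 change went from -0.17 to -0.08 (adjusted p = 0.294). After that correction, and with voom, 4 members of the list were higher and 0 lower. Of 20 genes of fatty acid and triglyceride synthesis 3 fell and 0 rose (0 higher and 3 lower over the list alone, camera adjusted p = 0.148): the desaturase SCD went from 75.4 ± 2.37 to 61.2 ± 4.70 FPKM (log2 -0.30, limma adjusted p = 0.00648), SREBF1 from 37.2 to 32.1 FPKM and DGAT1 from 9.89 to 8.36 FPKM. Each of SREBF1 and DGAT1 kept its call in 2 of the 6 such fits, with adjusted p up to 0.107 (without control replicate 3) and 0.12 (without control replicate 1). After GC and length correction both calls were lost, the log2 changes going from -0.21 to -0.13 for SREBF1 (adjusted p = 0.0854) and from -0.22 to -0.14 for DGAT1 (0.105), and 1 member of the list was lower. It was also 1 without control replicate 2, PPARG replicate 2 or PPARG replicate 3. In cholesterol synthesis 1 of 23 genes rose and 1 fell (2 higher and 2 lower over the list alone, camera adjusted p = 0.433). The synthase HMGCS1 rose from 9.69 to 11.5 FPKM, a call kept in 3 of the 6 fits. In cholesterol synthesis the count of higher and lower genes was 0 and 1 without control replicate 1, control replicate 3 or PPARG replicate 3 and 1 and 2 without control replicate 2.

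Several keratins of stratified epithelium fell while keratins of simple epithelium rose. KRT14 (chromosome 17, 41582279 to 41586921), the basal-layer keratin, went from 66.8 ± 2.92 to 32.1 ± 0.522 FPKM (log2 -1.03, limma adjusted p = 8.64e-08) and its partner KRT5 from 103.4 ± 3.03 to 75.5 ± 2.03 FPKM (-0.45, adjusted p = 0.000129). KRT17 (-0.34), KRT6A (52.3 ± 2.06 to 35.2 ± 2.60 FPKM, -0.56) and KRT16 (-0.65) fell too. KRT7 rose from 103.0 ± 7.36 to 142.2 ± 11.3 FPKM (0.46, adjusted p = 0.00125), KRT8 from 142.3 ± 1.16 to 179.2 ± 8.93 FPKM (0.33, adjusted p = 0.00106) and KRT19 from 6.70 ± 0.586 to 9.65 ± 0.216 FPKM (0.47, adjusted p = 0.000913). KRT13 and KRT18, chosen after their values were seen, had log2 changes of -0.28 and 0.22 (adjusted p = 0.0248 and 0.0112). KRT13 did not pass without control replicate 1, control replicate 2, PPARG replicate 2 or PPARG replicate 3 (adjusted p = 0.0896, 0.0709, 0.0633 and 0.0908), nor KRT18 without control replicate 1 (0.0589). KRT13 was also lost with no filter (0.123) and without the trend (0.0538), and KRT18 with no filter (0.052). KRT15, a basal keratin also chosen afterwards, was at 13.5 ± 0.375 and 12.5 ± 1.03 FPKM (adjusted p = 0.302). Among other keratins of stratified epithelium, chosen in the same way, KRT10 was at 11.4 and 11.1 FPKM (adjusted p = 0.777) and KRT80 rose from 58.7 to 66.4 FPKM (0.18, adjusted p = 0.0146), a call lost without control replicate 1 (0.0605) or PPARG replicate 2 (0.0631). KRT6A shares sequence with KRT6B and KRT6C, and KRT14 with KRT16 and KRT17, so reads may have been divided among them.

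**Figure D3:**
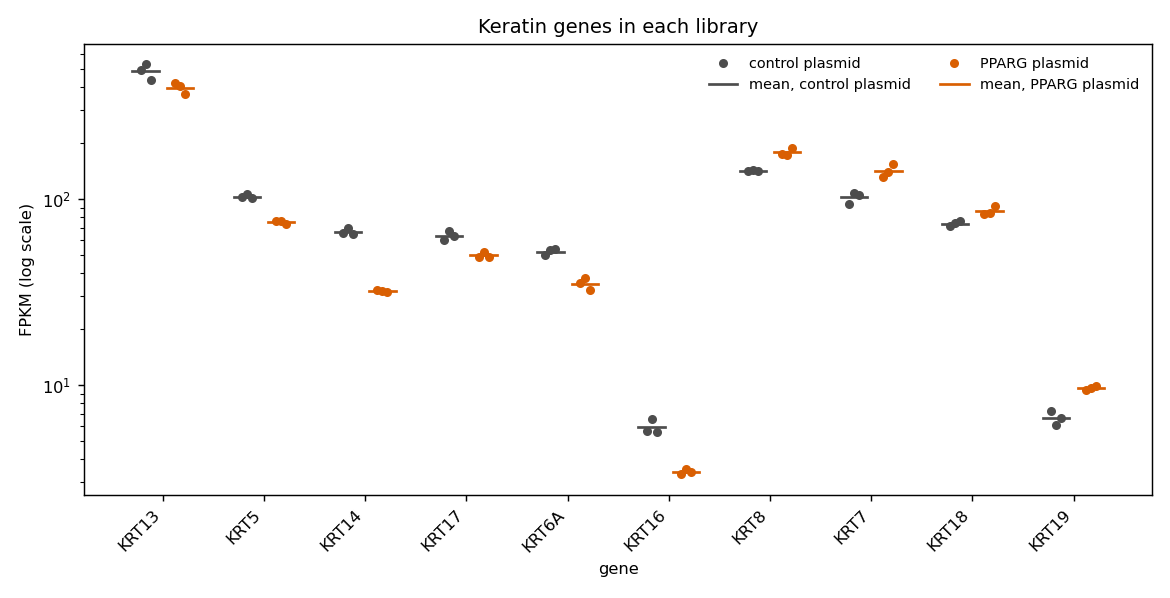
FPKM (log axis) of 10 keratin genes in each library, control plasmid in grey and PPARG plasmid in orange, with 1 dot per library and bars at the group means. The 6 keratins of stratified epithelium drawn on the left, without KRT10, KRT15 and KRT80, are lower in the PPARG libraries, KRT14 most (66.8 to 32.1 FPKM), and the 4 of simple epithelium on the right are higher.

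Calls among basal keratinocyte genes were all downward. Of the 22 genes in that list 11 were lower and 0 higher, with a median log2 fold change of -0.14, and 14 were lower when adjusted over the list alone. Its members with the smallest adjusted p were KRT14, KRT5, NGFR (10.9 ± 0.746 to 6.61 ± 0.668 FPKM) and KRT17. At the preset correlation camera gave an adjusted p of 8.69e-07, which held in 15 of 15 alternatives, but the adjusted p was 0.619 with an estimated correlation. The number of lower members was 6 without control replicate 1, and 7 without control replicate 3 or without PPARG replicate 3. TP63, the regulator of squamous identity, chosen after its values were seen, went from 27.2 ± 0.793 to 23.6 ± 0.408 FPKM (-0.20, adjusted p = 0.0138), a call lost without control replicate 1 (0.059) or control replicate 3 (0.0564). Most keratinocyte differentiation genes lay under the filter, 9 of 39 being tested. Of these 5 fell and 0 rose (KRT6A, KRT16, KRT13, PPL and TGM1), the transglutaminase TGM1 from 5.41 ± 0.412 to 4.01 ± 0.197 FPKM, with a list median of -0.26 and the same 0 and 5 calls adjusted over the list alone. For this list camera gave an adjusted p of 0.00146, and it was 0.568 with an estimated correlation. In the simple and luminal list 4 of 15 genes rose (KRT7, KRT8, KRT18 and KRT19) and 3 fell (PPL, CLDN4 and FGFR3), with 4 and 4 over the list alone, and the camera adjusted p was 0.429. The calls of CLDN4 and FGFR3 were each kept in 1 of 6 fits with a library left out (adjusted p up to 0.131, without PPARG replicate 3, and 0.142, without control replicate 1), and FGFR3 was chosen after its values were seen. For the simple and luminal list the count of higher and lower genes was 3 and 1 without control replicate 1 and 4 and 1 without control replicate 2, control replicate 3, PPARG replicate 2 or PPARG replicate 3. Of 22 junction genes 3 fell and 0 rose, among them the desmosomal cadherin DSG3 (23.0 ± 0.46 to 18.4 ± 1.2 FPKM, -0.31, adjusted p = 0.00481), with 1 higher and 6 lower over the list alone and a camera adjusted p of 0.704. For junction genes it was 1 and 1 without control replicate 1 and 0 and 1 without PPARG replicate 2 or PPARG replicate 3.

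More YAP and TGF-beta targets rose than fell, and more protease and matrix genes fell than rose. Members that did not pass were 13 of 19 and 10 of 20. Of 19 YAP and TGF-beta targets 5 rose (ANKRD1, CCN1, SKIL, AMOTL2 and ID2) and 1 fell, with a median log2 fold change of 0.10. ID2, chosen after its values were seen, kept its call in 1 of 6 fits with a library left out (adjusted p up to 0.0813, without control replicate 3). CCN1, a matricellular protein, went from 15.7 ± 1.26 to 22.0 ± 2.99 FPKM (0.45, limma adjusted p = 0.00662, lost with no filter at 0.0582) and AMOTL2, an angiomotin that binds YAP, from 17.8 ± 0.249 to 21.4 ± 0.899 FPKM (0.26, adjusted p = 0.00588). Adjusted over the list alone, 7 were higher and 1 lower. The number of higher and lower targets was 4 and 0 without control replicate 2, PPARG replicate 1 or PPARG replicate 3 and 5 and 0 without control replicate 3 or PPARG replicate 2. Camera gave an adjusted p of 0.00432, against 0.619 as the adjusted p with an estimated correlation, and the call was lost with the filter at a mean of 5 FPKM (0.0563). Of 20 protease and matrix genes 8 fell and 2 rose, with the same counts over the list alone and a median of -0.10. The inhibitor TIMP3 went from 31.6 ± 1.06 to 25.8 ± 0.972 FPKM (-0.28, adjusted p = 0.00389), LAMB3 also fell, and the collagenase MMP1 and the elastase MMP12, chosen after their values were seen, rose by 0.27 and 0.31. The camera adjusted p was 0.0265, and 0.681 as the adjusted p with an estimated correlation. It was 0.0628 without control replicate 3 and 0.0584 without PPARG replicate 3, and 0.0538 with no filter. The number of higher and lower protease and matrix genes was 0 and 3 without control replicate 1 or PPARG replicate 2, 0 and 5 without control replicate 2, 0 and 2 without control replicate 3, 0 and 7 without PPARG replicate 1 and 1 and 2 without PPARG replicate 3. The call of LAMB3 was kept in 2 of 6 fits with a library left out (adjusted p up to 0.0823, without control replicate 1), that of MMP1 in 0 of 6 (up to 0.136, without control replicate 2) and MMP12 in 1 of 6 (up to 0.161, without control replicate 1). Both MMP1 and MMP12 were also lost with no filter (0.0806 and 0.139), with the replicate block (0.0649 and 0.0536), after GC and length correction (0.0575 and 0.0647) and with voom (0.139 and 0.115), and in each of these 0 members of the list were higher.

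Of 19 mesenchymal transition genes 2 rose and 4 fell (2 higher and 6 lower over the list alone, camera adjusted p = 0.425). N-cadherin (CDH2) went from 6.88 ± 0.672 to 9.17 ± 0.425 FPKM (log2 0.37, limma adjusted p = 0.00588) and THBS1 from 7.55 ± 0.324 to 9.79 ± 0.765 FPKM (0.33, adjusted p = 0.00657), while the fibronectin receptor chain ITGA5 fell from 20.9 ± 0.587 to 17.7 ± 0.695 FPKM (-0.23), a call lost without control replicate 1 (adjusted p = 0.0551). For this list the number of higher and lower genes was 2 and 1 without control replicate 1, control replicate 3 or PPARG replicate 3 and 2 and 2 without PPARG replicate 2. Genes listed as fibroblast markers were mostly under the filter, 5 of 16 being tested. Of these 3 fell and 0 rose, with a median of -0.23 and 5 lower when adjusted over the list alone. Whether the cultures held any fibroblasts was not tested. C1R, a complement protease that epithelial cells also make, fell from 13.9 ± 1.26 to 9.94 ± 0.917 FPKM (-0.44, adjusted p = 0.00412), and COL1A1 was at 4.25 ± 0.144 and 3.42 ± 0.245 FPKM. The camera adjusted p was 0.00223, and the adjusted p was 0.568 with an estimated correlation. It was 0.0735 with no filter. The calls of COL1A1 and FBLN1 were kept in 2 and 0 of the 6 fits with a library left out. Among fibroblast markers the number of higher and lower genes was 0 and 1 without control replicate 1, PPARG replicate 2 or PPARG replicate 3. Of the leukocyte and endothelial markers 1 of 18 was tested, CSF1R at 1.81 ± 0.182 and 1.99 ± 0.0763 FPKM (adjusted p = 0.454).

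**Figure D4:**
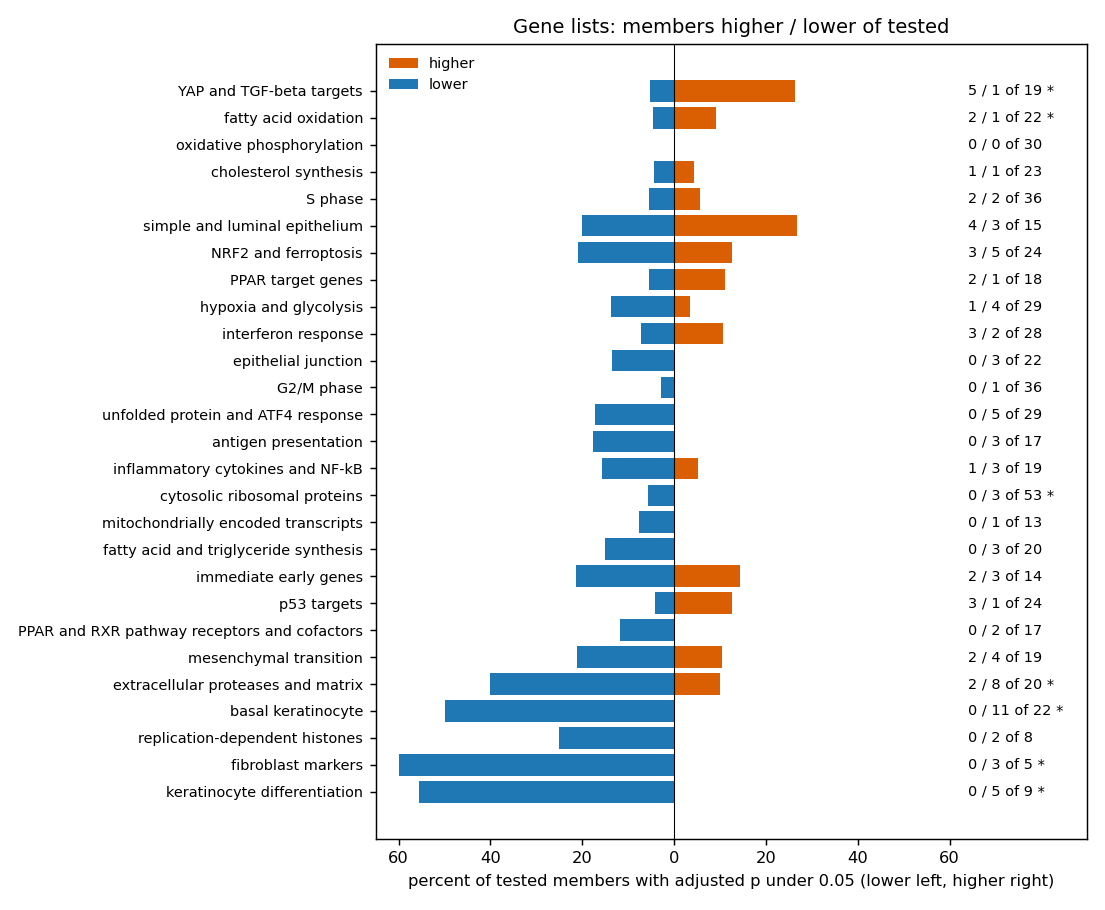
Share of each list's tested members (percent, horizontal axis) called higher (orange, to the right) or lower (blue, to the left) in the PPARG libraries, for the 27 lists tested, ordered by median log2 fold change; the counts stand at the right and an asterisk marks a camera adjusted p under 0.05 at the preset correlation. The basal keratinocyte list, with 11 of 22 members lower, and the YAP and TGF-beta list, with 5 of 19 higher, are among the 7 lists marked, none of which passes with an estimated correlation.

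Proliferation genes showed few calls. Of 36 S-phase genes 2 rose and 2 fell (2 higher and 2 lower over the list alone, camera adjusted p = 0.433): the polymerase subunit POLA1 went from 13.02 ± 0.632 to 15.6 ± 0.803 FPKM and the licensing factor CDT1 from 41.3 ± 1.13 to 35.1 ± 1.63 FPKM. POLA1 was lost with no filter (limma adjusted p = 0.0551) and CDT1 after GC and length correction (0.0637). The S-phase count of higher and lower genes was 1 and 1 without control replicate 1, control replicate 2, PPARG replicate 2 or PPARG replicate 3 and 1 and 3 without control replicate 3. Of 36 G2/M genes 1 fell and 0 rose, the kinesin KIF2C (39.8 ± 1.05 to 34.7 ± 1.16 FPKM, adjusted p = 0.0146), not past the threshold without control replicate 1 or control replicate 3 (0.0546 and 0.0597), with the same 0 and 1 over the list alone, and the camera adjusted p was 0.798. Of 24 p53 targets 3 rose and 1 fell (3 higher and 3 lower over the list alone, camera adjusted p = 0.704), with the nuclease AEN at 4.25 ± 0.112 and 5.70 ± 0.175 FPKM (adjusted p = 0.00351). The inhibitor CDKN1A fell from 20.6 to 17.5 FPKM, a call kept in 2 of 6 fits with a library left out (adjusted p up to 0.0832, without control replicate 1). For p53 targets the count was 2 and 0 without control replicate 1, control replicate 3 or PPARG replicate 3. Of 14 immediate early genes 2 rose and 3 fell (2 higher and 4 lower over the list alone, camera adjusted p = 0.484), FOSL1 among the first and ZFP36 (6.75 ± 0.519 to 5.20 ± 0.581 FPKM) among the second. ZFP36 was kept in 3 of those 6 fits (adjusted p up to 0.0767, without control replicate 1). For immediate early genes the count was 0 and 0 without control replicate 1, 2 and 1 without control replicate 2 or PPARG replicate 3, 1 and 2 without control replicate 3 or PPARG replicate 1 and 1 and 0 without PPARG replicate 2.

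Immune and stress lists had few calls, in both directions in some lists and only downward in antigen presentation and in the unfolded protein and ATF4 response. Of 28 interferon-response genes 3 rose and 2 fell (3 higher and 2 lower over the list alone, camera adjusted p = 0.484, upward, with a mean of 0.02 and a median of -0.00748), and OASL went from 3.88 ± 0.574 to 5.89 ± 0.895 FPKM. The count of higher and lower interferon genes was 1 and 0 without control replicate 1, control replicate 3 or PPARG replicate 3, 2 and 0 without control replicate 2 and 2 and 1 without PPARG replicate 2. Of 19 inflammatory genes 1 rose and 3 fell (1 higher and 6 lower over the list alone, camera adjusted p = 0.427), the cytokine IL1B from 13.2 ± 1.24 to 9.86 ± 0.73 FPKM (log2 -0.38, limma adjusted p = 0.00652, lost with no filter at 0.0518). For inflammatory genes it was 0 and 1 without control replicate 1, 0 and 2 without control replicate 2, 0 and 3 without control replicate 3 and 0 and 4 without PPARG replicate 1 or PPARG replicate 2. Of 17 antigen presentation genes 3 fell and 0 rose (0 higher and 5 lower over the list alone, camera adjusted p = 0.222), HLA-E from 132.9 ± 3.07 to 112.5 ± 3.31 FPKM (-0.24, adjusted p = 0.00504). HLA genes are similar in sequence and their reads may be divided. In antigen presentation the count was 0 and 1 without control replicate 1, PPARG replicate 2 or PPARG replicate 3. Of 29 hypoxia and glycolysis genes 1 rose and 4 fell (3 higher and 6 lower over the list alone, camera adjusted p = 0.716), including NDRG1 (20.1 ± 0.658 to 13.01 ± 1.2 FPKM, -0.59, adjusted p = 0.000246) and the aldolase ALDOC (11.5 ± 0.271 to 8.47 ± 0.697 FPKM, -0.41). In hypoxia and glycolysis it was 5 and 5 after GC and length correction, 1 and 2 without control replicate 1, 0 and 5 without control replicate 2, 0 and 4 without control replicate 3, 3 and 4 without PPARG replicate 1 and 0 and 3 without PPARG replicate 2 or PPARG replicate 3. Of 29 genes of the unfolded protein and ATF4 response 5 fell and 0 rose (0 higher and 6 lower over the list alone, camera adjusted p = 0.0785), CEBPB among them. Without control replicate 1, without PPARG replicate 3, with no filter and with voom that list's camera adjusted p was 0.0265, 0.0262, 0.0361 and 0.0465 (0.0262 to 0.22 over the alternatives). The list's fry adjusted p was 0.0273, and its camera adjusted p was 0.619 with an estimated correlation. Its count of higher and lower genes, however, was 0 and 2 without control replicate 1, control replicate 2 or PPARG replicate 3 and 0 and 3 without control replicate 3, PPARG replicate 1 or PPARG replicate 2. Of 24 NRF2 and ferroptosis genes 3 rose and 5 fell (4 higher and 5 lower over the list alone, camera adjusted p = 0.952, downward, with a mean of -0.03 and a median of 0.00218), the transferrin receptor TFRC from 48.9 ± 2.07 to 63.8 ± 2.88 FPKM (0.38, adjusted p = 0.000754) and AKR1C3 from 5.37 ± 0.591 to 3.93 ± 0.179 FPKM. AKR1C3 has near-identical relatives and was lost with no filter (adjusted p = 0.057). For the NRF2 and ferroptosis list the count was 1 and 2 without control replicate 1, 2 and 2 without control replicate 3 or PPARG replicate 3 and 2 and 3 without PPARG replicate 2.

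Ribosomal protein, mitochondrial and histone lists had few called members. Of 53 cytosolic ribosomal protein genes 3 fell and 0 rose, RPS27 from 247.1 ± 13.99 to 198.9 ± 9.76 FPKM (log2 -0.31, limma adjusted p = 0.00439), with the same counts over the list alone, and the list's median was -0.05. The camera adjusted p was 0.0442, and 0.831 as the adjusted p with an estimated correlation. It was 0.528 without control replicate 2, 0.793 without PPARG replicate 1, 0.0951 without PPARG replicate 2 and 0.0772 after TMM rescaling. The count of higher and lower ribosomal protein genes was 0 and 1 without PPARG replicate 2. Of 30 oxidative phosphorylation genes 0 were called by limma, over the list alone too, with 3 higher and 2 lower at an unadjusted p under 0.05, 0 by voom, and a camera adjusted p of 0.217 that became 0.0192 without PPARG replicate 1 (0.0192 to 0.696 over the alternatives). Their count of higher and lower genes was 1 and 1 without control replicate 2. Of 13 mitochondrially encoded transcripts 1 fell and 0 rose (1 higher and 1 lower over the list alone, camera adjusted p = 0.769): MT-ND4L went from 562.5 ± 15.0 to 454.8 ± 62.5 FPKM, a call kept in 1 of 6 fits with a library left out (adjusted p up to 0.0973, without control replicate 1). For mitochondrial transcripts the count was 0 and 0 without control replicate 1, control replicate 2, control replicate 3, PPARG replicate 2 or PPARG replicate 3 and 1 and 1 without PPARG replicate 1. Of 8 replication-dependent histone genes 2 fell and 0 rose (0 higher and 3 lower over the list alone, camera adjusted p = 0.0993), all 8 had negative log2 fold changes and the median was -0.15. Over the alternatives the camera adjusted p was 0.0146 to 0.359, under the threshold with the replicate block (0.0146) and without control replicate 3 (0.0368). H2AC6 went from 19.4 ± 1.12 to 15.8 ± 0.939 FPKM, a call lost without control replicate 1 (adjusted p = 0.0526). For histones the count was 0 and 0 without control replicate 1.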

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

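The GC and length correction, the same without PPARG replicate 3, and voom on implied reads were chosen after seeing the data; the others were fixed beforehand. Those meant for counts were not run, because the table holds FPKM. PPARG was higher under every alternative run, and 0 of the 1224 called genes changed sign in any of them. The kept signs say little. Changing the filter, the trend or the block leaves a gene's fold change as it is. For 1212 of the 1224 the libraries of the groups did not overlap, so leaving out a library could not turn the sign. With no filter 430 genes were called (165 higher, 265 lower), with more genes tested. After GC and length correction without PPARG replicate 3 it was 561 (287 higher, 274 lower). An adjusted p under 0.01 left 328 genes and a log2 fold change of at least 1 left 6. Leaving out each library in turn gave 472 to 1290 genes, 164 to 468 higher and 308 to 822 lower; the lowest was without control replicate 1. Residuals of libraries with the same replicate number correlated at 0.178, -0.00997 and -0.0111, and those with different numbers at -0.166 to 0.154. This does not settle whether the numbers pair the libraries. With the replicate block 1285 genes were called. Of 27 lists 7 passed at the preset correlation, 4 of 25 with a mean of at least 5 FPKM and 0 of 27 with an estimated correlation. Among those 7, the fry adjusted p was 0.00207 for fatty acid oxidation and 0.0174 for keratinocyte differentiation. It was 0.0267 for basal keratinocyte genes and 0.0273 for fibroblast markers. For protease and matrix genes, YAP and TGF-beta targets and ribosomal protein genes it was 0.0802, 0.0865 and 0.449. Of the results for called named genes, 1172 kept their side of the threshold, 248 lost it and 0 reversed. CFD, not called, changed sign to 0.0637 after GC and length correction and 0.0846 with PPARG replicate 3 also left out; the cause was not tested. Depth limits genes under the filter.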

Other observations

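The test of GC content on the share of lower genes and the test of genes under the filter were chosen only after the results were seen, and the keratins compared and both gene lists tested here were picked after the strongest genes had been seen, the lists without those genes. All genes given with values in this part, except PPARG, were chosen after their values were seen. Of the 10 splits of the 6 libraries into 3 and 3, the real 1 called 1224 genes and the highest of the others 0. With 10 splits a share under 0.05 cannot be reached. Every other split also put libraries of both groups on each side, so any group difference widened its spread and lowered its calls. The splits therefore do not decide whether the count arose by chance.

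RRS1, a factor of ribosome assembly, rose from 15.5 to 21.1 FPKM (log2 0.42, limma adjusted p = 0.00122). Of 79 other tested factors of ribosome biogenesis, not seen before, 34 were higher and 0 lower by limma (median log2 fold change 0.18, 76 of 79 positive; camera p = 3.1e-21, and 0.0777 with an estimated correlation). The number of higher factors was 13 without control replicate 1, 20 without control replicate 3, 20 without PPARG replicate 2 and 13 without PPARG replicate 3. Ribosomal protein genes did not rise with them: 3 of 53 were lower and 0 higher. Transcripts of biogenesis factors may thus be raised in the PPARG libraries, a hypothesis found and tested on the same data, and ribosome production was not measured.

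DBP (9.58 ± 0.325 to 6.05 ± 0.779 FPKM) and PER1 (10.4 ± 0.643 to 6.51 ± 0.348 FPKM), an output and a core repressor of the circadian clock, were among the strongest falls. Of 12 other clock genes 5 were lower and 0 higher (median -0.18, camera p = 0.000122, and 0.0521 with an estimated correlation), NR1D1 from 16.7 ± 0.781 to 11.5 ± 0.479 FPKM. The number of lower genes was 3 without control replicate 1, without control replicate 3 or without PPARG replicate 2. A difference in the time of harvest or of the last change of medium could give the same values and was not tested. ARRDC4, a relative of TXNIP that responds to the same glucose sensor, went from 6.76 ± 0.188 to 5.09 ± 0.561 FPKM (log2 -0.35, limma adjusted p = 0.00857, and 0.0547 with no filter).

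PPARG rose 34.2-fold while its known targets did not rise as a group. After GC and length correction the median log2 fold change of the tested targets was 0.034 (-0.0787 to 0.101). Over all tested genes the median ran only from 0.0139 at 32% to 41.8% GC to -0.0584 at 58.7% to 74.2%. A trend this small could hide only a small rise of the group. Its correction could hardly move the targets' median, so that value is no separate evidence on GC content. With a pseudocount of 0.1 the median was -0.00305 (-0.121 to 0.116). As 9 of the 18 tested targets were positive and 9 negative, that median could hardly move, so compression by the pseudocount was not decided. The ranges of medians here and below are 95% intervals over genes taken as independent. Loss of responding targets to the filter stays open: the 14 of 20 filtered targets with at least 10 implied reads had a median ratio of 0.937 (0.531 to 1.22). The 4 with at least 50 reads in each group were at 0.741 to 1.02, none clearly higher, but the other 10 ranged from 0.257 to 2.28, and at a median of 10.1 reads per library, under a limit of 20 set after the values were seen, the 14 were not taken to decide it. A receptor without added ligand may raise few targets, and neither ligand nor PPARG protein was measured here.

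Of keratins picked after the values were seen, 6 of stratified epithelium were lower and 4 of simple epithelium higher, their medians differing by 0.90 on the log2 scale. With KRT10, KRT15 and KRT80 added to the first set the difference was 0.74, so the pattern does not cover all stratified keratins. For the picked keratins the difference was 0.92 after GC and length correction and 0.81 without PPARG replicate 3. The GC trend over all tested genes was far smaller (medians of 0.0139 at 32% to 41.8% GC and -0.0584 at 58.7% to 74.2%), so its correction could hardly change the difference. As these keratins had been picked for opposite changes, leaving out 1 library could hardly remove it either. Neither value is counted as evidence against these explanations. The sums of KRT5, KRT6A, KRT6B and KRT6C and of KRT14, KRT16 and KRT17 changed by log2 -0.492 and -0.673. Because KRT5, KRT6A, KRT14, KRT16 and KRT17 had been picked as lower, these sums were bound to fall. They do not decide whether reads moved between similar keratins, and keratins outside the sums were not checked. The simple and luminal list did not pass (4 higher, 3 lower, camera adjusted p = 0.429), so a change of epithelial state is not shown, and a difference between the transfected cell pools stays open.

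More genes were lower than higher, 62.34% of calls. The share moved with scaling and filter, to 57.3% after TMM rescaling and 54.57% with a mean of at least 5 FPKM. After GC and length correction it was 48.91% (46.2 to 51.6), but 52.58% (49.8 to 55.4) with GC content and length first shuffled over genes. The parts of this drop due to GC content and to the centring that comes with the correction cannot be told apart. Calls did follow GC content: 94 were higher and 45 lower at 32% to 41.8% GC, against 67 and 342 at 58.7% to 74.2%. Spearman correlations with GC content were 0.066, 0.2 and 0.175 for control replicates 1, 2 and 3. For PPARG replicates 1, 2 and 3 they were -0.124, -0.0252 and -0.237. This trend thus went with the groups, and its cause was not tested. PPARG replicate 3 alone is argued against, the share being 65.26% (61.2 to 69.2) without it. The ranges in brackets in this paragraph are 95% binomial intervals over called genes taken as independent, so they leave out the spread between libraries. No biological explanation was tested.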
